A study of Mus musculus with 3 samples.

How the data were processed

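Epithelial cells of mouse large intestine, lower small intestine and upper small intestine were profiled by RNA sequencing, with 1 library per region. Per the labels' protocols, opened and washed intestines were shaken in 5 mM EDTA at 37 °C for 20 min, and the released cells were spun at 780 g for 5 min at 4 °C. RNA was extracted with an RNeasy kit and libraries were made with a TruSeq stranded mRNA kit, again per the labels. No cell sorting is described in the labels.

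The deposited values are 1 number per gene and library, taken here as FPKM, a read count divided by transcript length and library size. The unit was inferred, since the file headers give a library name and no unit. Cufflinks 2.2.1 is the only quantifier named per the submitters' processing notes, which also name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and the genome build mm10, without roles or order. The gene annotation, filters and the strand setting of counting are not given in the sources used here. The deposited FPKM of the 3 libraries had median ratios to their geometric mean of 1.00, 1.01 and 0.999 for large, lower and upper, while their sums were 521651, 646262 and 693218. They had therefore been brought to a common scale, or happened to share one, by a step not given in the sources used here. If genes shift on balance one way between regions, such scaling hides the shift. An exact 0 can be a failed estimate, since genes that every cell uses were at or near 0 in some libraries, so such genes are said to be listed at 0. Where strand was not used in counting, reads of overlapping or antisense genes cannot be told apart, and near-identical genes such as alpha-defensins can share reads.

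Of 24346 gene names, 23310 matched a gene symbol of GENCODE M21 (GRCm38, the same assembly as mm10), from which coordinates were taken, and 771 matched neither GENCODE nor RefSeq. Names of short RNA classes, such as microRNA and snoRNA, numbered 1307, and 7096 names were at 0 in all libraries. No pair of libraries held identical values.

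Depth was estimated from low values. In genes with 1 transcript of at least 1500 nt, FPKM times transcript length fell near whole multiples of a step of 0.118, 0.092 and 0.137 FPKM per read per kb in the large, lower and upper libraries. Within 0.15 read of a whole number were 78.2%, 74.2% and 77.0% of 376, 427 and 370 genes. A step fixed beforehand would give 30% by chance. Each step was fitted to these same values, so 30% is not the chance level of the fitted steps. These steps stand for about 8440000, 10870000 and 7330000 reads if FPKM was divided by each library's own read total. With the common scale described above, these totals are uncertain. Reads per gene follow from the step alone. Implied reads per gene, from the shortest transcript, gave Clopper-Pearson intervals at the 95% level on ratios between 2 libraries. They cover counting error alone, not differences between animals or preparations, and reads without molecular identifiers are not independent molecules. Recovery was too incomplete for a test on counts.

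Differences were taken as log2(FPKM + 1) of the first library minus the second, which understates differences of low genes. A gene was measured in a comparison at 1 FPKM or more in 1 of the 2 libraries, and was called higher or lower, by size and without a test, at an absolute difference of at least 1 (a 2-fold ratio of FPKM + 1). With 1 library per region no p-value, SD or standard error was computed. The comparisons were large against lower, large against upper and upper against lower small intestine, the level of Entpd8 in all 3, and genes at least 1 log2 unit above both other libraries.

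Gene lists, 32 in number, were fixed before the data were examined, as were the rules, the rule for named genes and all alternatives but 1. For each list the median difference of its measured members was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. Lists below the percentile 2.5 or above 97.5 were called apart, as a description of these libraries. Over the 3 comparisons 54 of 87 lists with at least 3 measured members were apart, 34 low and 20 high, where 4.35 would be by chance for independent lists. Some lists hold genes that other lists or cell types also express.

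The rule for named genes took every measured member of the nucleotide enzyme and purinergic lists, and from each other list up to 4 members of largest absolute difference per comparison. It also took the 8 genes of largest difference per direction at 10 FPKM or more, and the 8 with the widest margin in each region. The rule named 244 genes, 25 of them short RNA genes. Because short RNA genes filled most of the places for the largest differences, the same rule was also applied without them, a choice made after the data were seen, as was naming the genes lowest in 1 region. These additions brought the number to 263. Genes outside it are marked in the text as named or singled out after their values were seen. Some of the genes that the rule took are not reported here.

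The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 FPKM, 3 other scalings (to a common sum, to median ratios and to the upper quartile), a rule of size or margin of 2, random lists not matched on expression and, added after the data were seen, leaving out short RNA genes. The scripts were tested on simulated libraries of 16442 genes, short RNA genes left out, with counting noise and 200 genes changed by known folds. Between 14 and 23 of 16242 unchanged genes passed the rule of size, 90% to 93% of genes changed 3-fold were recovered and 100% of those changed 8-fold. Of 100 unshifted random lists 4 to 5 fell in the tails, a number that drawing them at random sets by construction. Of 100 lists with every member raised by 1 log2 unit, 100 fell in the upper tail. Both outcomes check the scripts alone, and lists of genes that vary together were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.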

Results

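RNA sequencing was performed on epithelial cells released from the large intestine, the lower small intestine and the upper small intestine of mice. Each region was represented by 1 library, so none of the differences given here has a replicate check, and they describe these libraries. The labels do not say how many animals contributed to a library. The upper small intestinal library alone carries a strain entry, which describes a mouse model of colorectal cancer. If that entry is true, strain and region cannot be told apart in comparisons with that library. The files listed 24346 genes. Of these, 11589 reached 1 FPKM (fragments per kilobase of transcript, scaled by library size) in the large intestine, 11595 in the lower small intestine and 11491 in the upper small intestine. By the spacing of low values, 1 FPKM in a transcript of 2 kb stood for about 16.9, 21.7 and 14.7 reads in the same order. This spacing implied about 8440000, 10870000 and 7330000 counted reads, totals that are uncertain if the values were rescaled between libraries. The 10 most abundant genes held 7.79% of the summed FPKM in the large intestine, 17.3% in the lower and 19.7% in the upper small intestine. The largest value of the upper library, 49507 FPKM, belonged to the microRNA Mir1892. The share and the sum of that library thus rest in part on a short RNA gene. Gene values below are in FPKM. Lists of 3 values run in the order large intestine, lower small intestine, upper small intestine, and log2 differences are on the log2(FPKM + 1) scale. A value of 0 means that a gene was listed at 0, which can be a failed estimate.

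The study concerns E-NTPD8, an ectoenzyme that hydrolyses extracellular ATP, and the ATP-gated channel P2X4 in the inflamed colon, so their genes were examined first along the intestine. Entpd8, which encodes E-NTPD8, was expressed in all 3 epithelia, at 61.6, 52.03 and 65.1 FPKM. Its large to lower ratio was 1.18 (1.09 to 1.29), its large to upper ratio 0.946 (0.863 to 1.03) and its upper to lower ratio 1.25 (1.15 to 1.37). The brackets, here and below, are 95% Clopper-Pearson intervals from implied reads (about 1009, 1098 and 927 for Entpd8) and cover counting error alone. The lower library thus lay below the others by more than counting error, and a difference between the large and upper libraries was not detectable at this depth. None of the 3 differences reached the 2-fold rule of size used here. The log2 difference from the upper library was -0.08 as deposited and 0.33 when each library was rescaled to the same sum, so its sign was not fixed by these data. Entpd8 lies on chromosome 2 at 25080304 to 25085716 (mm10, plus strand, protein coding, ENSMUSG00000036813.11). P2rx4, which encodes P2X4 and lies on chromosome 5 at 122707544 to 122729738 (plus strand), was highest in the large intestine at 78.1 FPKM. It was 2.92 (2.55 to 3.36) times its level in the lower and 3.46 (2.92 to 4.12) times its level in the upper small intestine.

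Other members of the list of enzymes acting on extracellular nucleotides differed between regions in both directions. Whether each enzyme acts outside or inside the cell was not measured here, so the counts describe the list and not ectoenzymes alone. Of 19 measured members of this list, Entpd8 included, 4 were higher and 6 lower in the large than in the lower small intestine, and 4 were higher and 8 lower than in the upper. The medians of -0.01 and -0.08 lay at or above 5152 and 3650 of 10000 expression-matched random lists. The enzymes higher in small intestine included Alpi, an intestinal alkaline phosphatase, at 6.76, 153 and 613 FPKM. Enpp7, also on the list and counted as lower in both comparisons, was at 0.188, 195 and 239.9 FPKM. It encodes an intestinal alkaline sphingomyelinase, so it is not an example of an enzyme acting on nucleotides. Ada, which deaminates adenosine, was at 2.63, 112 and 125 FPKM, Enpp3 at 0.962, 15.99 and 55.3 FPKM and Bst1, an ADP-ribosyl cyclase, at 0.051, 20.6 and 65.4 FPKM. Akp3, a second intestinal alkaline phosphatase on chromosome 1, was almost restricted to the upper library at 0.074, 1.08 and 286 FPKM. Entpd5 was higher in the large than in the lower small intestine, at 107, 32.7 and 57.9 FPKM, and Enpp5 was higher than in both small intestinal libraries, at 25.8, 6.74 and 6.58 FPKM. Nt5e, which converts AMP to adenosine, was at 20.5, 10.7 and 6.96 FPKM and passed the rule of size against the upper library alone. Cd38 was at 73.6, 74.2 and 31.3 FPKM.

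Among purinergic receptors and ATP release genes, 2 of 11 measured members were higher and 3 lower in the large than in the lower small intestine, and 3 of 10 were higher and 3 lower than in the upper. Slc17a9, the vesicular nucleotide transporter, was at 48.6, 5.16 and 2.15 FPKM, and its large to lower ratio was 9.42 (7.85 to 11.5). Panx1, a channel that can release ATP, was lower in the large intestine, at 11.9, 40.02 and 25.7 FPKM. P2ry6 was at 7.85, 3.59 and 1.18 FPKM, P2ry2 at 6.79, 13.3 and 7.56 FPKM and P2rx7 at 2.42, 3.59 and 2.42 FPKM. Adora2b, an adenosine receptor, was highest in the upper small intestine at 1.20, 1.39 and 10.2 FPKM. P2ry10, a receptor of lymphocytes, was at 1.29, 9.18 and 5.80 FPKM, and T cell markers as a list were also lower in the large intestine, with median differences of -3.04 and -3.00. The receptor list's medians of -0.42 and -0.23 stayed within the middle 95% of random lists, and against the upper library its mean had the opposite sign (0.15).

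**Figure D1:**
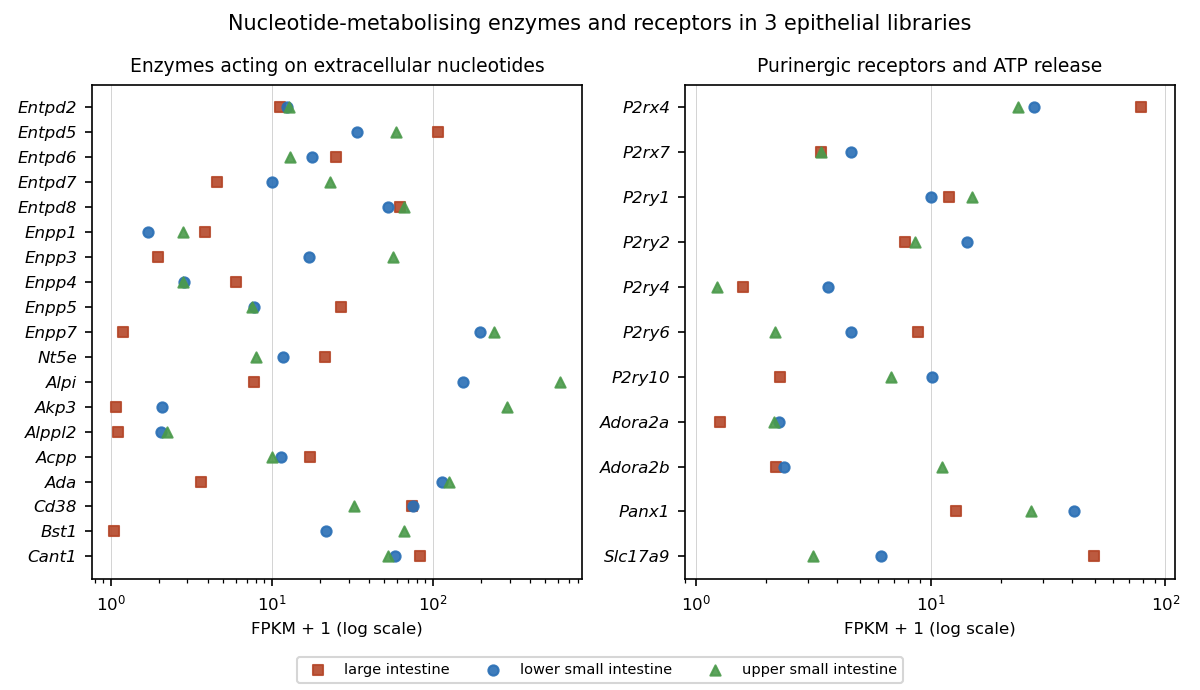
FPKM + 1 on a log axis, 1 point per library, with no error bars because each region has 1 library. The left panel shows each measured member of the list of enzymes acting on extracellular nucleotides. The right panel shows each measured purinergic receptor or ATP release gene. Entpd8 lies between 52.0 and 65.1 FPKM in all 3 libraries. P2rx4 and Slc17a9 are highest in the large intestine, and Alpi and Ada in the small intestine. The left panel also holds Enpp7, a sphingomyelinase on the list.

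The large intestine was then compared with each part of the small intestine. Against the lower part, 1207 genes were higher and 1298 lower among 12376 measured genes. Against the upper part, 1387 were higher and 1441 lower among 12350. Higher in large intestine were thus 48.2% and 49.0% of the genes past the rule of size. When each library was rescaled to the same sum these shares became 63.7% and 68.3%, with all-gene medians moved by 0.29 and 0.38. In simulated libraries with counting noise alone, 14 and 23 of 16242 unchanged genes passed the rule. Of genes with a 3-fold difference, 90% and 91% were recovered. The simulation left out short RNA genes, which the counts above include. Without them 1171 genes were higher and 1262 lower against the lower part, and 1354 higher and 1419 lower against the upper. Both comparisons use the same large intestinal library, so they are not independent. Leaving aside short RNA genes, the genes with the largest differences in favour of the large intestine in both comparisons included Car1, carbonic anhydrase 1, at 6414, 0.172 and 0.257 FPKM and Mptx1, a pentraxin, at 3341, 2.40 and 1.69 FPKM. Tgm3, a transglutaminase, was at 352, 0.021 and 0 FPKM, Wfdc2 at 383, 0.504 and 0.251 FPKM and Sult1a1, a sulfotransferase, at 433, 0.723 and 0.432 FPKM. Slc6a14, an amino acid transporter, was at 382, 6.15 and 0.039 FPKM and Sval1 at 686, 4.11 and 1.23 FPKM.

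Genes of nutrient digestion and uptake were lower in the large intestine. Of 21 genes for brush-border sugar and peptide digestion and uptake, 20 were lower than in the lower part and none higher, and 20 were lower than in the upper part and 1 higher, Mep1a, at 132 FPKM against 42.9 FPKM, named after its values were seen. Their medians of -3.66 and -4.58 lay below all 10000 random lists in both comparisons. Anpep, which encodes aminopeptidase N, was at 6.34, 2086 and 2250.4 FPKM, Sis, encoding sucrase-isomaltase, at 5.93, 491 and 936 FPKM and the amino acid transporter Slc6a19 at 1.42, 237 and 249 FPKM. Lct, encoding lactase, was at 0.201, 33.4 and 356 FPKM. Of 20 lipid absorption genes, 18 were lower and 1 higher in each comparison, with medians of -4.26 and -5.16, again below all random lists. The apolipoprotein genes Apoa1 and Apoa4 were at 7.27, 4122 and 7061 FPKM and 1.12, 504 and 2797 FPKM, and Fabp1, which binds fatty acids in the cytosol, at 1.15, 329.8 and 7255 FPKM. Of 8 bile acid and cobalamin genes, 7 were lower in the large than in the lower small intestine (median -3.32, below all random lists). Against the upper part 3 of 7 were higher and 4 lower (median -1.32, at or above 4 of 10000). The cobalamin receptor genes Amn and Cubn were at 3.25, 74.2 and 71.3 FPKM and 2.95, 55.6 and 61.9 FPKM.

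Iron, calcium and vitamin genes were divided. Of 12 measured, 3 were higher and 1 lower in the large than in the lower small intestine, and 2 were higher and 4 lower than in the upper, with medians of 0.34 and -0.38 inside the middle 95% of random lists. Slc40a1, the iron exporter ferroportin, was higher in the large intestine at 85.4, 15.1 and 18.8 FPKM, and so was the calcium channel gene Trpv6 at 5.21, 0 and 0.554 FPKM. Rbp2, which binds retinol, was lower at 32.2, 551 and 4561 FPKM. S100g, encoding the calcium-binding protein calbindin-D9k, was at 229, 10.2 and 188 FPKM.

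Of 19 genes for ion and water transport of the large bowel, 15 were higher in the large intestine in each comparison and none lower. The medians of 2.17 and 2.68 lay above all 10000 random lists. Besides Car1, the water channel gene Aqp8 was at 247, 0.066 and 0.197 FPKM and Slc26a2, a sulfate transporter, at 229, 52.5 and 34.8 FPKM. Atp12a, a proton pump of the distal colon, was at 86.6 FPKM in the large intestine and Best2, a bestrophin channel, at 26.7 FPKM, and both were listed at 0 in the other libraries. Hsd11b2, which inactivates glucocorticoids, was at 143, 11.7 and 3.75 FPKM. Of 15 genes of fatty acid oxidation and ketogenesis, 3 were higher in each comparison and none lower. Their median against the lower part was 0.55, at or above 9987 of 10000 random lists, and against the upper part 0.05, at or above 8051. Acads, a short-chain acyl-CoA dehydrogenase, was among them in both comparisons, at 135, 41.5 and 40.7 FPKM.

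Genes of drug and xenobiotic metabolism differed in opposite directions in the 2 comparisons. Against the lower small intestine 11 of 22 were higher and 6 lower in the large intestine (median 1.16, above all 10000 random lists). Against the upper small intestine 1 of 24 was higher and 14 lower (median -1.67, below all random lists). Cyp2c55 was at 852, 2.17 and 22.5 FPKM and the alcohol dehydrogenase gene Adh1 at 775, 16.9 and 524 FPKM. Cyp3a11, Cyp3a25 and Cyp2b10 were at 0.059, 11.8 and 379.5 FPKM, 0.32, 23.99 and 228 FPKM and 0, 13.3 and 264 FPKM.

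All 16 measured Paneth cell genes were lower in the large intestine in both comparisons, with medians of -8.72 and -8.25, below all random lists. Lyz1, the lysozyme gene of Paneth cells, was at 5.26, 4824 and 4151 FPKM. The alpha-defensin genes Defa24, Defa17 and AY761184 were at 9.47, 9947 and 10287 FPKM, 0, 544 and 719 FPKM and 0.747, 1834 and 4492 FPKM, and Defa6, outside the list, at 15.9, 18619 and 19046 FPKM. Reads may be shared among near-identical alpha-defensin genes, so the value of any 1 of them is uncertain. Other epithelial defence genes were divided. Of 17 measured, 5 were higher and 8 lower than in the lower part, and 5 were higher and 6 lower than in the upper, with medians of -0.19 and 0.03 inside the middle 95% of random lists. Against the upper part the mean of -0.32 had the opposite sign. The C-type lectin genes Reg3b and Reg3g were lower in the large intestine at 1002, 22050 and 8893 FPKM and 114, 12929 and 3945 FPKM. Nos2 was at 0.144, 114 and 11.9 FPKM and Duoxa2, a maturation factor for dual oxidase, at 3.94, 109 and 7.16 FPKM. Saa1, encoding serum amyloid A1, was higher in the large intestine at 1328, 337 and 0.944 FPKM.

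More goblet cell genes were higher than lower in the large intestine, 5 of 13 against the lower part with 1 lower and 9 of 13 against the upper part with none lower. The medians were 0.91, at or above 9999 of 10000 random lists, and 1.75, above all of them. Muc2, the main secreted intestinal mucin, was at 1128, 329.6 and 151 FPKM, Klk1 at 1196, 77.5 and 48.7 FPKM and Clca1 at 825, 415 and 198 FPKM, whereas Tff3, at 992, 2215 and 1835 FPKM, passed the rule as lower against the lower part and not against the upper. Enteroendocrine genes were divided by hormone, with 3 of 15 higher and 6 lower against the lower part (median -0.11, at or above 2538 of 10000). Against the upper part 2 of 16 were higher and 5 lower (median -0.51, at or above 40). Insl5 was at 49.5 FPKM in the large intestine and listed at 0 in the others, and Pyy, encoding peptide YY, was at 108, 28.9 and 3.02 FPKM. Gip, Cck and Sst were lower in the large intestine at 0, 21.2 and 151 FPKM, 1.58, 9.95 and 62.2 FPKM and 6.42, 28.8 and 49.8 FPKM. Tuft cell markers were low throughout. None of 5 measured passed the rule against the lower part and 2 of 4 were lower against the upper, among them Alox5ap at 0.593, 2.06 and 3.11 FPKM. Their medians were -0.43 and -0.84, inside the middle 95%.

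Stem cell markers did not stand apart as a list, with 1 of 12 higher and 2 lower in each comparison and medians of -0.17 and -0.18 inside the middle 95% of random lists. Olfm4, a marker of small intestinal crypt base cells, was at 0.305, 396 and 579 FPKM, Sox9 at 26.9, 11.4 and 9.62 FPKM and Lgr5 at 3.78, 5.02 and 3.68 FPKM. Cell cycle genes were lower in the large intestine, 14 of 18 against the lower and 12 of 18 against the upper part, with none higher. Their medians of -1.34 and -1.07 lay below all random lists. Birc5 was at 17.2, 64.5 and 61.1 FPKM, Rrm2, a subunit of ribonucleotide reductase, at 5.31, 24.04 and 19.8 FPKM and Mcm5, of the replicative helicase, at 7.37, 26.2 and 22.9 FPKM. All 10 measured members of the posterior Hox list were higher in the large intestine in both comparisons. The medians of 3.22 and 3.85 lay above all random lists. Hoxb13, on chromosome 11 at 96194316 to 96197447 (plus strand), was at 236 FPKM in the large intestine and listed at 0 in both small intestinal libraries. Hoxd13 and Hoxa13, at 20.7 FPKM and 14.7 FPKM, were also listed at 0 there. Of 12 transcription factors of the proximal bowel and absorptive cells, 5 were lower against the lower part (median -0.32, at or above 461 of 10000). Against the upper part 7 of 14 were lower and 1 higher (median -1.91, below all random lists). Gata4 was at 0.137, 16.1 and 58.3 FPKM, Maf at 1.68, 90.5 and 79.4 FPKM and Creb3l3 at 1.31, 55.2 and 155 FPKM.

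More innate sensor genes were higher than lower in the large intestine, 6 of 16 against the lower part with 1 lower and 7 of 16 against the upper part with none lower. The medians of 0.47 and 0.37 lay at or above 9969 and 9828 of 10000 random lists. Both left the upper tail with a filter of 5 FPKM, and the second also without a filter. The Toll-like receptor genes Tlr1, Tlr4 and Tlr5 were at 32.4, 6.90 and 2.70 FPKM, 5.33, 0.508 and 0 FPKM and 4.12, 0.478 and 0.042 FPKM. Tight junction genes mostly missed the rule, with 1 of 15 higher and 2 lower against the lower part and 2 higher and 1 lower against the upper. Their medians were 0.16 and 0.25, inside the middle 95%. Cldn8 was higher in the large intestine at 17.6, 0.782 and 0.058 FPKM and Cldn15 lower at 92.4, 246 and 348 FPKM. Of 10 genes common to intestinal epithelium, 2 were lower against the lower part, Vil1 and Krt20, at 278, 913 and 974 FPKM and 361, 968 and 702 FPKM (median 0.02, with a mean of -0.26). Against the upper part 2 were higher and 2 lower (median 0.37, at or above 9871 of 10000 random lists), among them Krt18 at 316, 232 and 151 FPKM. That place was lost against random lists not matched on expression. Housekeeping genes had medians of -0.01 and -0.11, and of the 12 Actb and B2m were lower than in the lower small intestine, at 1077, 2471 and 2139 FPKM and 516, 1898 and 1960.1 FPKM. Immediate early and heat shock genes, which respond to tissue dissociation, had medians of 0.41 and 0.43, at or above 9876 and 9921 of 10000 matched random lists. The second left the upper tail against unmatched lists. Of 13 such genes 2 and 3 were higher in the large intestine, including Dusp1 at 153, 75.3 and 63.7 FPKM, and none lower. The heat shock genes were divided, since Hspa1a at 64.3, 113 and 78.9 FPKM, Hspa1b and Dnajb1, singled out after their values were seen, lay below both other libraries without passing the rule.

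All 7 MHC class II genes were lower in the large intestine in both comparisons, with medians of -4.29 and -2.96, below all random lists. Cd74, the invariant chain, was at 59.2, 1453 and 716 FPKM, H2-Aa at 30.1, 615 and 242 FPKM and Ciita, the class II transactivator, at 0.769, 18.03 and 7.62 FPKM. B2m, which pairs with MHC class I, was lower as well, as given above. Markers of immune cells, some of which reside within the epithelium, were also lower in the large intestine. Of 13 T cell and intraepithelial lymphocyte markers, 13 were lower against the lower and 12 against the upper part, with both medians (-3.04 and -3.00) below all random lists. Gzma was at 3.09, 334 and 357 FPKM, Ccl5 at 7.43, 273 and 251 FPKM and Cd8a at 0.75, 15.9 and 17.4 FPKM. Of 10 myeloid markers 9 were lower against the lower part (median -1.96, below all random lists), and 5 of 8 against the upper (median -1.44, at or above 4 of 10000). Tyrobp was at 2.44, 15.03 and 31.2 FPKM and Itgax at 0.228, 4.21 and 3.78 FPKM. All 5 measured B and plasma cell markers were lower against the lower part (median -1.70, at or above 10 of 10000). Jchain, the joining chain of secreted immunoglobulins, was listed at 0 in the large intestine and was at 22.5 and 28.1 FPKM in the lower and upper small intestine.

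Markers of other tissues were low. Of 12 fibroblast and smooth muscle markers 3 were measured, Tagln, Vim and Dcn, at 7.83, 2.56 and 1.64 FPKM, 3.89, 10.3 and 6.79 FPKM and 1.93, 3.29 and 2.02 FPKM. Their medians were -0.55 against the lower part and -0.04 against the upper, where the mean was 0.34. Of 7 endothelial markers Pecam1 alone reached 1 FPKM, at 1.31, 1.37 and 0.93 FPKM, and none of 7 neuron and glia markers did. Of 3 measured red blood cell markers 2 were lower in the large than in the lower small intestine, Hba-a1 and Hbb-b2, at 6.16, 13.4 and 7.46 FPKM and 1.03, 3.58 and 2.68 FPKM. That list's medians were -1.003 and -0.24, inside the middle 95% of random lists. Pancreatic acinar markers were measured almost solely in the upper library, where 12 of 15 reached 1 FPKM. Against it 11 of these 12 were lower in the large intestine (median -2.56, below all random lists). Ctrl was the 1 acinar marker measured against the lower part, at 0.641, 1.61 and 6.64 FPKM.

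**Figure D2:**
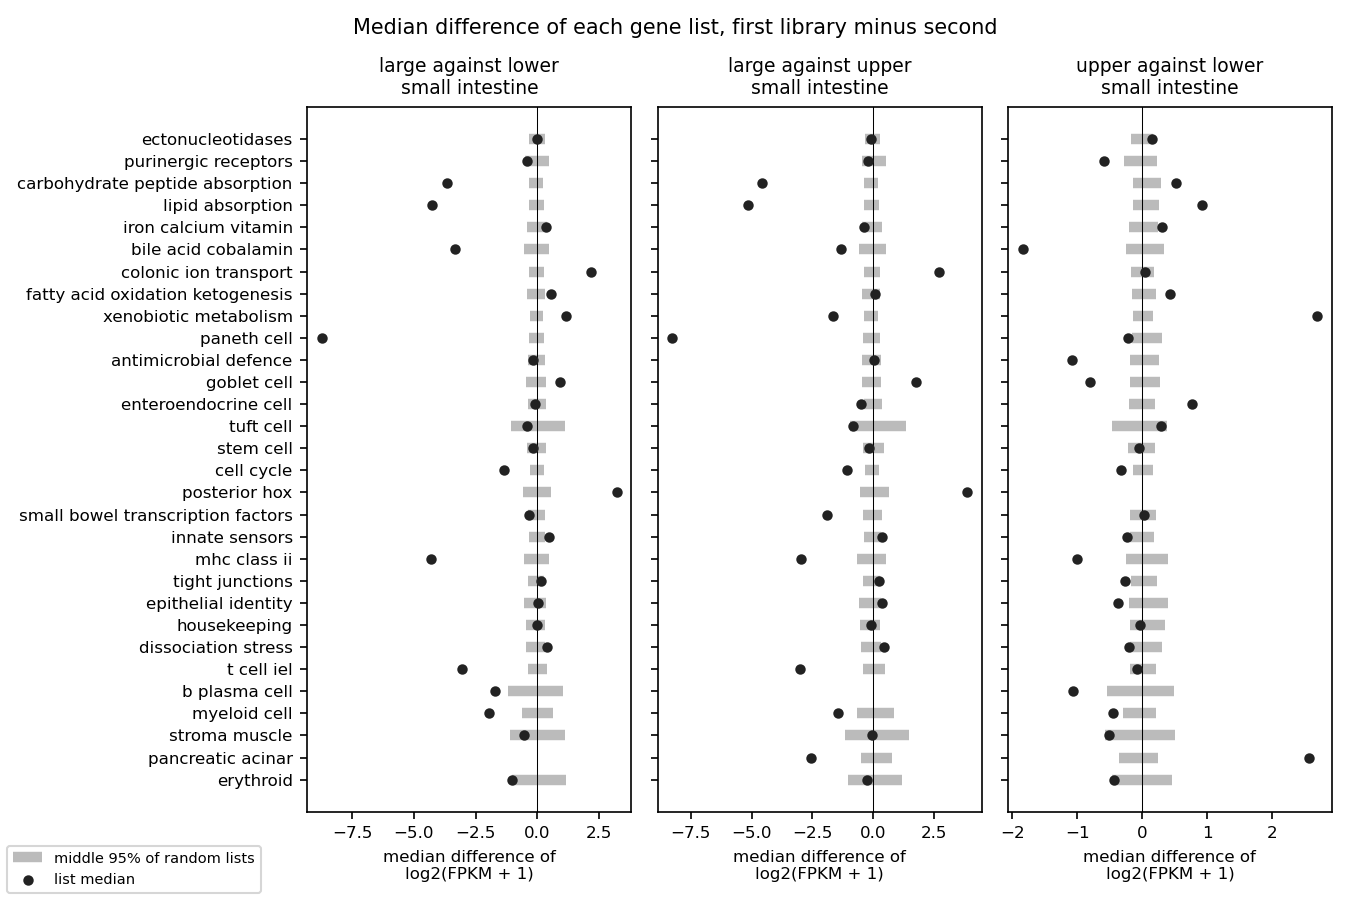
Median difference of log2(FPKM + 1) of each gene list (points), first library minus second, for the 3 comparisons, with grey bars for the middle 95% of 10000 random lists of the same size matched on expression. The right panel spans a narrower range than the others. Lists with under 3 measured members have no point, and absorption, Paneth cell, MHC class II and T cell lists lie left of the bars for the large intestine, and ion transport and posterior Hox lists lie right of them.

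The upper and lower parts of the small intestine differed less. Of 11941 measured genes, 468 were higher in the upper and 349 in the lower part, 6.84% of the genes in all, against 20.2% and 22.9% in the comparisons with the large intestine. The upper library accounted for 57.3% of the genes past the rule, or 49.4% with the libraries rescaled to the same sum. That rescaling moved the all-gene median from -0.03 to -0.12. In the simulation, which left out short RNA genes, 17 of 16242 unchanged genes passed the rule and 93% of 3-fold differences were recovered. Without short RNA genes the counts in the data were 451 higher in the upper and 311 in the lower part. Across genes the log2 values correlated with r = 0.924, a description over genes, which are not independent replicates. The genes with the largest differences in favour of the upper part, leaving aside short RNA genes, included Reg1, Akp3, Fabp1 and the cytochrome P450 gene Cyp2c66. Reg1, a secreted lectin also made in the pancreas, was at 1199 FPKM against 5.69 FPKM, Fabp1 at 7255 FPKM against 329.8 FPKM and Cyp2c66 at 49.6 FPKM against 0.296 FPKM. Fabp6, the ileal bile acid binding protein gene on chromosome 11 at 43596049 to 43601540 (minus strand), stood furthest in favour of the lower part, at 7245 FPKM against 0.416 FPKM. Tmigd1, Suox and Mgat4c followed among others, at 258 FPKM against 8.45 FPKM, 118 FPKM against 4.28 FPKM and 76.7 FPKM against 3.25 FPKM.

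More nutrient genes were higher than lower in the upper part. Of 21 sugar and peptide genes 8 were higher and 2 lower (median 0.52, at or above 9996 of 10000 random lists). Slc2a2, which encodes the glucose transporter GLUT2, was 11.1 (10.3 to 11.9) times as high in the upper part and Lct 10.7 (10.2 to 11.2) times. Of 20 lipid genes 9 were higher and none lower (median 0.92, above all random lists), including Apoa4 with a ratio of 5.55 (5.42 to 5.67) and Cd36 with 9.50 (7.17 to 12.7). Iron, calcium and vitamin genes were higher in 4 of 11, with none lower (median 0.30, at or above 9887 of 10000). S100g was 18.4 (13.95 to 24.9) times as high and Slc46a1, the proton-coupled folate transporter, 14.3 (11.7 to 17.9) times. Xenobiotic genes were higher in 19 of 24, with none lower (median 2.69, above all random lists), including Cyp3a11 at 379.5 FPKM against 11.8 FPKM and Adh1 at 524 FPKM against 16.9 FPKM. Fatty acid oxidation genes had a median of 0.43, at or above 9998 of 10000, with 2 of 15 past the rule, among them Pdk4 at 8.47 FPKM against 0.647 FPKM. Pancreatic acinar markers were higher in the upper library in 11 of 12 (median 2.56, above all random lists). Ctrb1 and Cela2a reached 15.5 and 13.4 FPKM there and were listed at 0 in the lower part. Bile acid and cobalamin genes were lower in the upper part in 6 of 8, with none higher (median -1.84, below all random lists). Slc10a2, the ileal bile acid transporter, was at 0.618 FPKM against 102 FPKM and Fgf15, the bile acid induced hormone, at 0.078 FPKM against 7.52 FPKM.

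Among nucleotide genes, 5 of 19 enzymes were higher in the upper part and 1 lower (median 0.16, at or above 9696 of 10000). These were Entpd7, Enpp3, Alpi, Akp3 and Bst1 on the higher side, with an Alpi ratio of 4.01 (3.86 to 4.16), and Cd38 on the lower side with a ratio of 0.421 (0.388 to 0.457). The purinergic list's median of -0.58 lay below all random lists, with 1 of 11 higher, Adora2b, and 2 lower, P2ry4 and P2ry6. Ion and water transport genes of the large bowel had a median of 0.05 and a mean of -0.14, with 1 of 14 higher, Slc9a3, and 2 lower, Slc5a8 and Hsd11b2. Both measured members of the posterior Hox list were lower in the upper part, among them Hoxb9, listed at 0 against 6.65 FPKM. Transcription factors of the proximal bowel were higher in 4 of 14 with none lower (median 0.03, at or above 6427 of 10000). Onecut2 was at 11.6 FPKM against 0.134 FPKM, Pdx1 at 9.19 FPKM and listed at 0 in the lower part, and Gata4 had a ratio of 3.63 (3.24 to 4.08).

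Defence genes outside the Paneth list were lower in the upper part in 9 of 18 and higher in 2 (median -1.09, below all random lists). Saa1 was at 0.944 FPKM against 337 FPKM, Duoxa2 at 7.16 FPKM against 109 FPKM and Nos2 at 11.9 FPKM against 114 FPKM. Paneth cell genes were lower in 4 of 16 and higher in 1 (median -0.23, at or above 29 of 10000), with Lyz1 at 4151 FPKM against 4824 FPKM. MHC class II genes were lower in 4 of 7 with none higher (median -1.004, at or above 1 of 10000), with H2-Aa at 242 FPKM against 615 FPKM. Beside these, B and plasma cell markers were lower in the upper part in 3 of 5 (median -1.06, at or above 6 of 10000), among them Cd79a at 0.336 FPKM against 2.55 FPKM. Myeloid markers were lower in 2 of 10 and higher in 1 (median -0.46, at or above 19 of 10000), but the median was 0.0861 with a filter of 5 FPKM. None of 13 T cell markers passed the rule (median -0.08, at or above 2328 of 10000). Innate sensors had a median of -0.23, at or above 83 of 10000, a place lost with a filter of 5 FPKM, with 1 of 14 higher, Il18, and 2 lower, Tlr1 and Tlr2.

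Goblet cell genes were lower in the upper part in 3 of 12 with none higher (median -0.80, below all random lists), with Muc2 at 151 FPKM against 329.6 FPKM and Agr2 at 494 FPKM against 1082 FPKM. Enteroendocrine genes were higher in 5 of 15 and lower in 1 (median 0.77, above all random lists). Gip had an upper to lower ratio of 7.16 (5.94 to 8.62), Cck 6.24 (4.83 to 8.13) and Ghrl, encoding ghrelin, 6.44 (3.45 to 12.1), whereas Pyy was at 3.02 FPKM against 28.9 FPKM. No tuft cell, stem cell, cell cycle, tight junction, general epithelial, housekeeping, dissociation stress, stromal or red blood cell gene on the lists passed the rule. Of these lists, the medians of cell cycle (-0.32), tight junction (-0.27), general epithelial (-0.37) and dissociation stress genes (-0.20) lay at or above 1, 15, 12 and 214 of 10000 random lists. The last place was lost against unmatched lists. The medians were 0.29 for tuft cell, -0.05 for stem cell, -0.04 for housekeeping (mean 0.04), -0.51 for stromal and -0.44 for red blood cell genes, inside the middle 95%.

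A last comparison asked which genes were highest in 1 region, at least 1 log2 unit above both other libraries. There were 986 in the large intestine, 166 in the lower and 334 in the upper small intestine, or 961, 139 and 325 without short RNA genes, an alternative chosen after the data were seen. With the libraries rescaled to the same sum, which raises large intestinal values by construction, the numbers were 1712, 197 and 306. The 2 differences behind each call share a library, so these counts describe these libraries. Besides Car1, the large intestinal genes with the widest margin included Sycn, which encodes syncollin, a protein of pancreatic secretory granules, at 939.7, 0 and 2.52 FPKM. In the lower small intestine Fabp6 was followed by Atp6v0c-ps2 at 0.663, 173 and 0.272 FPKM, a pseudogene whose values are uncertain beside those of its parent gene Atp6v0c at 167, 23.4 and 191 FPKM. Plb1, a phospholipase, was at 0.391, 163 and 8.89 FPKM and Slc34a2, a phosphate transporter, at 2.28, 58.5 and 4.52 FPKM. Ndufs5, a subunit of mitochondrial complex I, was at 0.005, 12.6 and 0.005 FPKM, although cells in general use this gene, so values near 0 in these files can be failed estimates. In the upper small intestine Reg1, on chromosome 6 at 78422711 to 78428667 (plus strand), had the widest margin outside short RNA genes, followed by Akp3, Gm766 at 0, 0.531 and 131 FPKM, Cyp3a11, Fabp1, Cyp2c29 at 0, 0.213 and 21.8 FPKM, Cyp2b10 and Ctrb1. Over the 3 pairwise comparisons, short RNA genes held 31 of the 48 places among the largest differences. Mir762 at 0, 0 and 16403 FPKM and Mir677 at 3349, 0 and 3854 FPKM were examples, and such values rest on short transcripts.

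**Figure D3:**
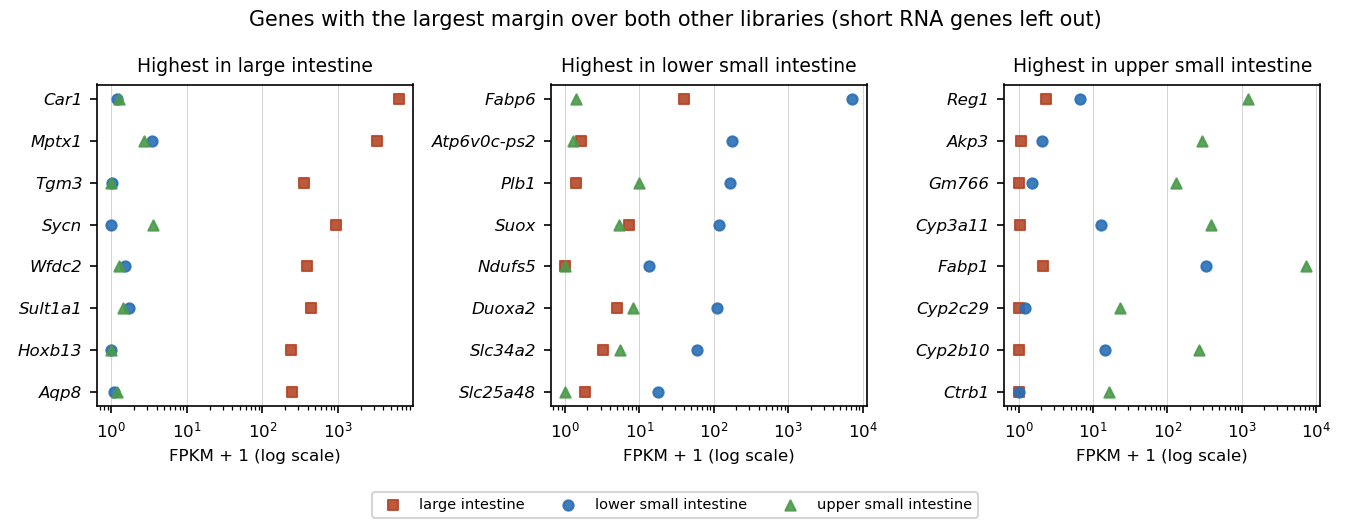
FPKM + 1 on a log axis for the 8 genes with the widest margin over both other libraries in each region, short RNA genes left out, 1 point per library and no error bars because each region has 1 library. Car1, Fabp6 and Reg1 have the widest margins in the large, lower small and upper small intestine.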

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

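The count of genes past the rule of size depended mostly on the pseudocount, the scaling and the rule itself. With a pseudocount of 5, which shrinks differences of low genes by construction, 611 genes were higher and 682 lower in the large than in the lower small intestine, 721 higher and 810 lower than in the upper, and 283 were higher in the upper and 163 in the lower small intestine. Genes highest in 1 region then numbered 495, 92 and 207 in large, lower and upper. A pseudocount of 0.1 gave 536 genes higher in the lower than in the upper part. A rule of 2 log2 units, stricter by construction, gave 399 and 472, 479 and 523, and 135 and 97 genes in the same order of comparisons, and a margin of 2 gave 327, 50 and 88 genes highest in 1 region. Rescaling each library to the same sum raises large intestinal values by construction, since that library has the lowest sum. It gave 2070 and 2537 genes higher in the large than in the lower and upper small intestine and 1712 genes highest in the large intestine. It placed Entpd8 0.55 above the lower and 0.33 above the upper library, the second with a sign opposite to the deposited scale. No other count moved by over 1.5 times under any alternative run, the one without short RNA genes included, which was chosen after the data were seen. Dropping the filter on low values could not alter these counts, since a difference of 1 already needs 1 FPKM in a library. None of the named genes past the rule reversed, and the most that left it was 28 of 189, for the large against the lower part with a pseudocount of 5. Of the 54 lists apart from random lists, all kept their tail with both other pseudocounts and all 3 other scalings. Rescaling a library shifts a list and its random lists by nearly the same amount, so the scalings could hardly alter its place by construction. The tail was kept by 53 without a filter, by 51 against unmatched lists and by 48 of 52 with a filter of 5 FPKM. With that filter the myeloid list's median in the upper against the lower part turned to 0.0861, over fewer members by construction, and innate sensors lost their tail in all 3 comparisons. Innate sensors also lost it against the upper library without a filter, and against unmatched lists the general epithelial list (large against upper) and dissociation stress (large against upper, upper against lower) did. The cause was not tested. Depth limits low genes, since 1 FPKM stood for about 15 to 22 reads in a transcript of 2 kb. No paired analysis was possible because each region has 1 library, and for the same reason no library could be left out.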

Other observations

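All tests reported in this part were chosen after the results were seen. A set of 83 genes without short RNA genes was lowest in the lower small intestine, at least 1 log2 unit below both other libraries and thus higher both above and below it along the gut. By the same margin 933 genes were lowest in the large and 148 in the upper small intestine. Lists of 3 values again run large, lower small and upper small intestine, and the genes named here were chosen after their values were seen. Adh1 was at 775, 16.9 and 524 FPKM, S100g at 229, 10.2 and 188 FPKM and Papss2, which makes the sulfate donor of sulfotransferases, at 234, 37.2 and 453 FPKM. Enzymes that act on drugs and esters were among them, with Gstm1 at 212, 14.5 and 105 FPKM, Ces1d at 54.4, 0.382 and 15.5 FPKM and Aadac at 48.3, 6.73 and 104 FPKM. Both sides of this pattern share the lower library and are not independent.

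Among the genes lowest in the upper small intestine, Pyy was at 108, 28.9 and 3.02 FPKM, the monocarboxylate transporter gene Slc5a8 at 104, 39.7 and 4.24 FPKM, Sprr2a3 at 104, 20.4 and 1.95 FPKM and Ddah1, which degrades methylated arginines, at 11.5, 13.6 and 0.496 FPKM. Saa1, Mgat4c and Sprr2a3 shared an order from large to lower to upper, with Saa1 at 1328, 337 and 0.944 FPKM and Mgat4c at 124, 76.7 and 3.25 FPKM.

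Pancreatic acinar markers stood out in the upper library. In the upper small intestine 12 of 15 acinar markers reached 1 FPKM, with 1 in the other libraries together, and their median was 4.85 FPKM there and 0 in both others, which is what carried-over pancreatic tissue or free pancreatic RNA may give. Reg1, however, was 77.2 times the highest acinar marker of that library (Ctrb1 at 15.5 FPKM), which argues against acinar cells as the whole source of Reg1, since they bring their abundant enzyme transcripts with them. The ratio of Reg1 to these enzymes in pancreatic tissue was not measured here, so the argument holds only as far as acinar cells do not hold Reg1 so far above their enzymes, and free pancreatic RNA was not tested apart. Epithelial expression of Reg1 that differs by region stays open as a hypothesis, with the strain entry of the upper library and the lack of replicates. Sycn, also known from the pancreas, was instead highest in the large intestine at 939.7, 0 and 2.52 FPKM, and no explanation of this is offered here.

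Defence genes outside the Paneth list and MHC class II genes tended to be higher in the lower than in the upper small intestine. The 18 measured defence genes had a median difference of 1.09 log2 units, with 9 past the rule and Reg1 and Reg4 past it the other way, and the 7 class II genes a median of 1.004, with 4 past the rule and the others at 0.82 or more. A larger share of T cells in the lower library is argued against as the whole explanation of either list, because T cell markers differed by a median of 0.085 (quartiles -0.10 and 0.24). Paneth markers differed by 0.225 (quartiles -0.075 and 0.853), with 4 of 16 past the rule and 1 the other way. A larger share of Paneth cells cannot be told apart from other explanations, since the medians of both lists lie above that of the Paneth markers by 0.863 and 0.778, less than the 0.928 between the quartiles. B and plasma cell markers differed by 1.06 (quartiles 0.436 and 1.08), which is consistent with a larger share of B cells behind the class II genes, but the median level of these 5 markers was 2.55 FPKM and Jchain, the most abundant, was higher in the upper library (28.1 against 22.5 FPKM). Myeloid markers differed by 0.46 (quartiles 0.10 and 0.84) at a median level of 4.31 FPKM. At such low levels neither B and plasma nor myeloid cells can be excluded for the defence genes, nor myeloid cells for the class II genes. A response of the epithelium itself in the lower small intestine is a candidate explanation that no test here addressed, and the strain entry of the upper library stays open too.

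Some of the widest differences between libraries may come from quantification. Of 92 short RNA genes that reached 10 FPKM in a library, 79.3% (73) were listed at 0 in another, against 0.886% (65 of 7333) of other genes, which is consistent with few reads on short transcripts. Atp6v0c was lowest in the lower small intestine, with a highest to lowest ratio of 8.16, where its pseudogene Atp6v0c-ps2 was highest. The sum of both was 168, 196 and 191 FPKM, a highest to lowest ratio of 1.17, which is consistent with reads of 1 gene assigned to the other. No biological explanation was tested for either pattern.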
